A study of Mus musculus with 19 samples.

How the data were processed

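Genomic DNA of metaphase II mouse oocytes (strain background C57BL6/129) was measured by post-bisulfite sequencing on a HiSeq 4000 in 19 libraries of 10 oocytes each, per the labels' protocols. Cumulus cells had been removed by pipetting after hyaluronidase, per the same protocols. Control mice received 500 µl of DMSO per litre of water, and bottles were changed every 5 days. The submitters' processing notes name Trimmomatic (version not given), Bismark (version given as 12.5) and mm10, which were taken as the tools for trimming and for alignment and calling. Their settings and any removal of duplicate reads were not stated. The name of each file states that lambda control sequence was excluded. Each deposited file lists CpG sites with a position, the fraction of calls that were methylated, and the counts of methylated and unmethylated calls. Per the labels' genome build the positions are on mm10, and the authors' deposited fraction equals methylated calls over all calls at the site. The deposited counts combine both strands of a site, as adjacent positions were absent. No filter on depth was seen, since sites with a single call were present in every library.

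All values below were computed from these call counts with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3; figures were drawn with matplotlib 3.10.9. The union of sites over libraries held 18420829 positions, 18420542 of them on nuclear chromosomes. Mitochondrial calls were 5.52% to 29.5% of a library's calls. The level of a library was the share of its nuclear calls that were methylated. The plan had been to take all calls, and the nuclear share was chosen once the totals per chromosome had been seen; the level with mitochondrial calls was kept as an alternative. Nuclear calls numbered 312695 to 12257342 per library. The 95% confidence intervals are Wilson score intervals for a library's nuclear level and exact binomial intervals for imprint regions and H19. A count of 0 was taken to allow up to 3 calls. Chromosome sequences, strands and exons were not used here. Promoters, exons, introns and sequence-defined CpG islands were therefore replaced by gene ends (1 kb to either side of both ends of a gene) and by CpG-dense regions (at least 8 sites of the union within 200 bp, 3928597 sites in all). Gene positions came from the RefSeq genes of GRCm38.p6, the assembly that mm10 names. The H19 region was taken 2 to 5 kb beyond the higher-coordinate end of the gene. The Tet2 interval was the longest run of sites without a call in any knockout library, and was also chosen without the libraries then counted in it.

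Group comparisons of the level of a library used exact two-sided permutation tests, with Benjamini-Hochberg adjustment over the 9 comparisons between groups. Each factor was also tested over the 3 strata of the other factors, permuting within strata, and 2 interactions were tested in the same way. For gene bodies, methylated and unmethylated calls of each of 21627 protein-coding genes were summed per library. A gene was tested when every library of the comparison had at least 10 calls in it. The edgeR quasi-likelihood F test was applied to the paired methylated and unmethylated counts, with a coefficient per library and the group effect on their ratio, and adjusted p-values of at most 0.05 were called. Adjusted p-values of genes are from edgeR unless limma is named, and differences are of group means in percentage points. Limma was run on the logit of the level with 0.5 calls added to each count.

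The comparisons, tests, named-gene rule and 9 gene lists were fixed before the data were examined. The lists, with the number of symbols found among those listed, were maternal imprints (14 of 14), paternal imprints (3 of 3), oocyte genes (27 of 28), methylation machinery (14 of 15), sirtuin and antioxidant genes (27 of 27), granulosa and cumulus genes (20 of 20), germline and meiosis genes (22 of 22), polycomb-bound developmental genes (25 of 25) and spindle, cohesion and checkpoint genes (23 of 24). The symbols H1foo, Stella and Survivin were not found. Tet2 was named first in each comparison, then the 10 largest rises and the 10 largest falls among called gene bodies whose groups did not overlap, then called members of the lists. Where fewer than 5 gene bodies passed, the 5 list members with the largest difference were named as values that did not pass. In the comparison of resveratrol and control in 6-month knockout, 1 gene that the rule took is not reported here. List levels were pooled over gene bodies, and over CpG-dense regions within 1 kb of the gene for the imprint lists. Enrichment of lists among called genes used Fisher's exact test with the other tested genes as background. The reference libraries for baseline levels were 4 deep libraries outside the 6-month groups (10-month wild type resveratrol 1 and 2 and knockout resveratrol 2 and 3); 25473 of 26327 windows of 100 kb had at least 20 calls in them. Imprint regions at 90% or more in the reference libraries (8 of 14) were chosen after the planned list had been examined.

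The edgeR test was run on simulated counts for 5 of the 9 comparisons, with 200 changed genes in each. The other 4 comparisons and the interactions were not simulated. Counts were drawn at the depth of the real libraries. The spread was a single value per comparison, estimated from genes at intermediate levels in the resveratrol group, or in the knockout group for genotype. That value served all genes and both groups, so the recovery does not reflect groups that differ in spread. In the simulation of the 6-month knockout comparison of resveratrol and control (15595 genes), changes of 20 and 40 points were recovered in 0% and 4% of genes, with 0 false calls. That simulation made 4 calls in all, where the real comparison called 1339, 612 of them with at least 20 points. Recovery rates therefore hold for the simulated settings and are not the power of the real tests. The numbers of false calls were 7 in the 6-month wild type comparison of resveratrol and control, 8 in the 6-month control comparison of genotypes, and 0 in the 10-month knockout comparison of resveratrol and control and in the 10-month resveratrol comparison of genotypes. The alternatives tried for the genome-wide level were autosomes only, the mean of per-site levels, sites with at least 5 calls, sites with a call in every library, and the replicate number as a block. For gene bodies they were minimums of 1, 5 and 20 calls, all 7 groups in 1 fit, limma with and without centring, a difference of at least 20 points, windows of 100 kb, the replicate block, and exclusion of sites above the 99.9th percentile of depth. Each library was also left out in turn for both. Alternatives added after the data had been seen were the level with mitochondrial calls, the mean over 100-kb windows covered in every library, strata without the 6-month knockout controls, left-out libraries for classes and lists, and the X chromosome relative to the autosomes.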

Results

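CpG methylation was measured in 19 post-bisulfite libraries of metaphase II mouse oocytes, each made from 10 oocytes, in 7 groups that combined age, Tet2 genotype and resveratrol in the drinking water. Resveratrol is a plant polyphenol studied as an activator of sirtuins, and Tet2 is 1 of the enzymes that oxidise methylated cytosine. At 6 months there were 3 libraries in each of 4 groups: wild type control, wild type resveratrol, Tet2 knockout control and Tet2 knockout resveratrol. At 10 months there were 2 wild type resveratrol, 2 knockout control and 3 knockout resveratrol libraries, and no 10-month wild type control was analysed here. Treated mice received 30 mg of resveratrol per litre from 2 months of age, and control mice received its solvent. Per library, the nuclear CpG calls numbered 340709 to 436041 in the 6-month wild type controls, 312695 to 4048818 with resveratrol in 6-month wild type, 4941065 to 12257342 in the 6-month knockout controls and 3658940 to 7506751 with resveratrol in 6-month knockout. At 10 months they numbered 8617723 to 9617539 in wild type resveratrol, 818040 to 4357497 in knockout controls and 1356626 to 8508490 in knockout resveratrol libraries. Each covered site carried 1.05 to 1.55 calls on average, so levels were pooled over gene bodies, regions or the genome. The widest 95% Wilson score interval of a library's nuclear level was 36.9% to 37.2%, in 6-month wild type control 3. Intervals cover counting error only, and only if calls are independent. The libraries carried no molecular identifiers and removal of duplicate reads was not stated, so the intervals may be too narrow. The p-values measure the spread between these samples, as the labels did not state whether each came from separate animals.

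The targeted gene was examined first. Tet2 (gene ID 214133) spans positions 133463677 to 133545136 of chromosome 3 in mm10. Between positions 133485578 and 133488970, a run of 48 CpG sites over 3393 bp carried 0 calls in all 11 knockout libraries, where 288 calls would have come at the wild type rate. The 8 wild type libraries held 115 calls there. These were 38 and 33 in 10-month wild type resveratrol 1 and 2, 4, 0 and 9 in 6-month wild type controls 1 to 3, and 29, 0 and 2 in 6-month wild type resveratrol 1 to 3. The 2 wild type libraries without a call had expected numbers of 1.71 and 1.49, so their depth could not check their labels. The rest of the gene held 31 to 493 calls in each knockout library, the next longest run without knockout calls covered 6 sites, and the longest run without a wild type call covered 22. The interval was chosen for its lack of knockout calls, as the position of the deletion was not stated in the labels, so the 0 is part of its definition. Chosen in the other 10 knockout libraries instead, it spanned 48 to 50 sites and held 2 calls in 6-month knockout control 2 (58.5 expected), 1 in 6-month knockout resveratrol 1 (17.5 expected) and 0 in each of the other 9 when left out. The upper 95% limit of a wild type share was then 7.37% to 76.7%, if calls are independent.

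**Figure D1:**
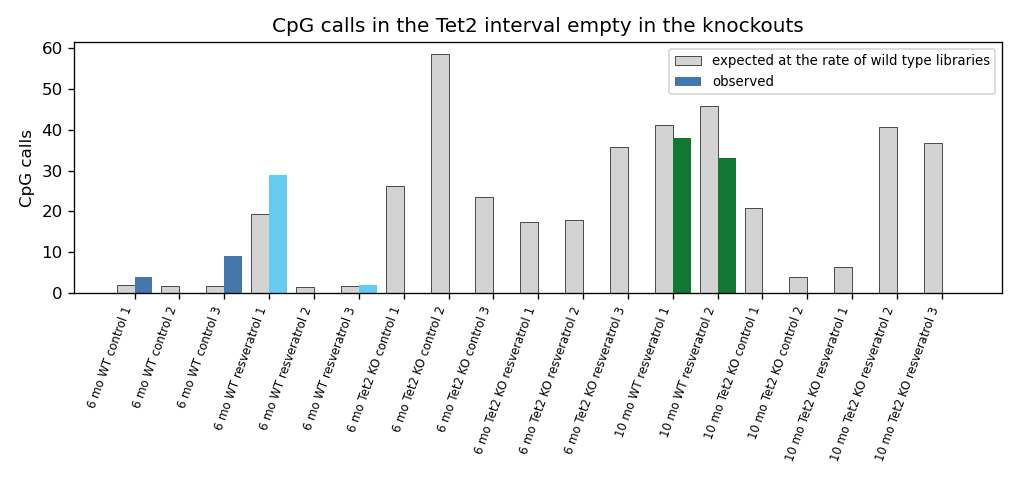
CpG calls inside the Tet2 interval of 48 sites (vertical axis, number of calls) in each of the 19 libraries (horizontal axis), with bars for the calls observed and for the calls expected at the rate of the wild type libraries. All 11 knockout libraries held 0 calls by the choice of the interval, against 288 expected.

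Genome-wide methylation lay near the same level in 6 of the 7 groups and was higher in the 6-month Tet2 knockout controls. Those controls averaged 45.1% ± 3.34 (SD, n = 3), with libraries at 44.4%, 48.7% and 42.2%. The 6-month group means were otherwise 36.1% ± 2.67 (SD, n = 3) in wild type controls, 35.4% ± 4.16 (SD, n = 3) with resveratrol in wild type and 36.9% ± 0.595 (SD, n = 3) with resveratrol in knockout. At 10 months they were 34.6% ± 1.28 (SD, n = 2) in wild type resveratrol, 35.9% ± 0.401 (SD, n = 2) in knockout controls and 36.7% ± 0.316 (SD, n = 3) in knockout resveratrol libraries.

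**Figure D2:**
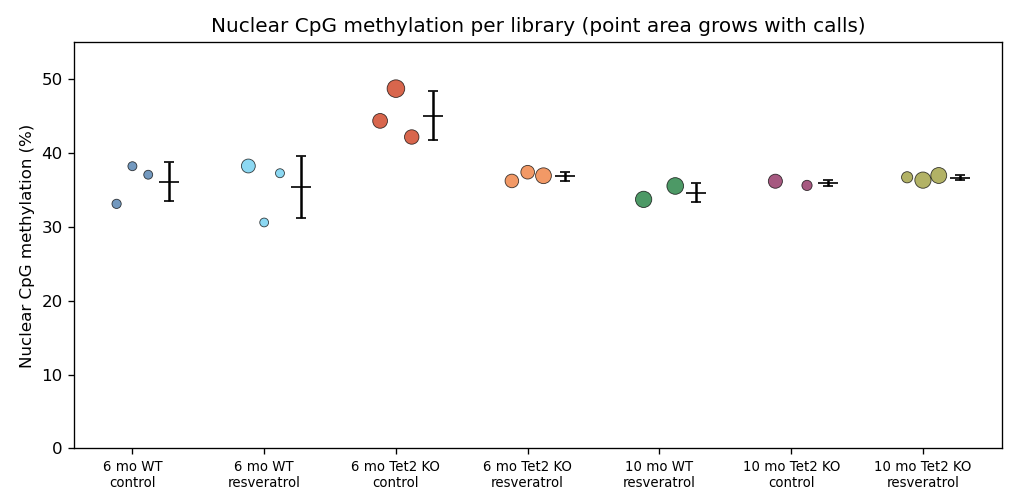
Nuclear CpG methylation level (vertical axis, percent of calls) of each library (points, with area growing with the number of calls) in the 7 groups (horizontal axis), with group means and bars of 1 SD. The 6-month knockout controls sit between 42.2% and 48.7%, above every other library.

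The first question was whether oocyte methylation differed with resveratrol in each genotype and age. In 6-month knockout oocytes, resveratrol and control libraries differed in 1339 gene bodies, of which 93 were more and 1246 less methylated with resveratrol. The genes that fell were those with little methylation elsewhere in the data: their median level was 3.70% with resveratrol, 24.4% in the controls and 4.79% in 4 deep reference libraries outside these groups. Those that rose had medians of 94.0%, 71.8% and 84.5% in the same order. Genome-wide the level was 36.9% with resveratrol and 45.1% in controls, a difference of −8.23 points ± 1.96 (SE, n = 3 and 3), and the groups did not overlap. The intergenic level was 26.8% ± 1.17 (SD, n = 3) with resveratrol and 40.4% ± 5.44 (SD, n = 3) in controls, and that of the X chromosome was 45.8% ± 1.67 and 53.1% ± 3.79.

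Imprint regions, and CpG-dense regions chosen by their level in the 4 reference libraries, differed in the same libraries. The level of these regions in somatic cells was not measured here. At 8 maternal imprint regions (Kcnq1ot1, Mcts2, Nap1l5, Nnat, Peg10, Peg13, Peg3 and Plagl1), which carry full methylation in grown oocytes and partial methylation in somatic cells, the knockout controls read 79.2%, 74.1% and 86.5% over 279, 738 and 223 calls. The knockout resveratrol libraries read 97.5%, 96.3% and 97.0%, and every other library with calls there read at least 91.5%, among them the 4 reference libraries by which the regions were chosen. Upstream of H19, unmethylated in oocytes, 9 of 56 calls (16.1%) were methylated in the controls, all of them in control 2. In that library 9 of 40 calls gave 22.5% (exact 95% binomial interval 10.8% to 38.5%, if calls are independent), while controls 1 and 3 held only 10 and 6 calls. With resveratrol 1 of 63 calls (1.59%) was methylated there. CpG-dense regions at 90% or more in the reference libraries read 88.4% ± 2.67 (SD, n = 3) in controls and 95.1% ± 0.748 with resveratrol, and the 3 controls lay below the 12 other libraries that had no part in choosing the regions (93.8% to 95.8%). Dense regions at 10% or less read 6.48% ± 1.69 in controls (5.15% in control 3) and 2.49% ± 0.194 with resveratrol, but high values were not limited to the knockout controls there: 6-month wild type controls 2 and 3 read 6.74% and 5.96%, and wild type resveratrol 3 read 5.81%.

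**Figure D3:**
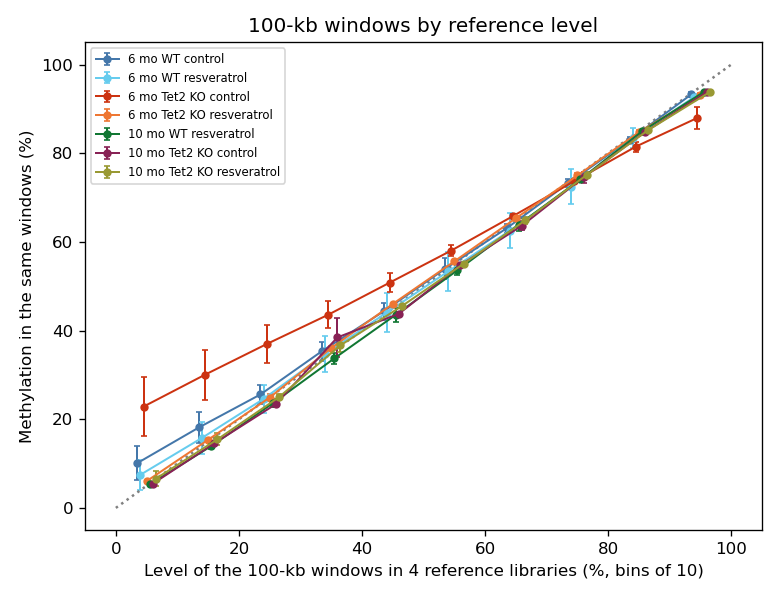
Group mean methylation (vertical axis, percent, bars of 1 SD) of 100-kb windows binned by their level in 4 reference libraries (horizontal axis, percent). In the lowest bin of 3213 windows the 6-month knockout controls averaged 22.8% against 6.03% with resveratrol and 10.1% in the 6-month wild type controls, and in the highest bin of 1016 windows 88.0% against 93.1%.

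Tet2 itself averaged 32.8% ± 4.98 with resveratrol and 58.2% ± 20.3 in controls (SD, n = 3 in each group, as for the genes that follow), which did not pass (adjusted p = 0.157). The largest rise was in Tcp1, a subunit of the cytosolic chaperonin (chromosome 17, 12916329 to 12925067), at 89.4% ± 5.73 with resveratrol and 19.3% ± 12.9 in controls (adjusted p = 0.0125). Ptcd3, of the mitochondrial ribosome (chromosome 6, 71880638 to 71908773), rose from 44.2% ± 14.5 to 99.3% ± 1.28 (adjusted p = 0.00702). Timm17b, of the inner membrane translocase, rose by 46.8 points. The rises of Pdcd5, Hdgf, Pcmtd2, Kpna1 (a nuclear import receptor), Errfi1 (an inhibitor of the EGF receptor) and Btbd6 were 61.5, 60.3, 52.9, 49.3, 46.5 and 46.1 points. The largest fall was in the zinc finger gene Zfp422 (chromosome 6, 116624016 to 116628999), from 64.1% ± 13.7 to 2.76% ± 3.48 (adjusted p = 0.00543). Cyp2g1, an olfactory cytochrome P450, fell by 58.1 points, Slfn4 fell by 54.4 points, the mucin glycosyltransferase gene Gcnt3 fell by 52.1 points and the epithelial keratin gene Krt4 fell by 48.2 points. Eif4e1b, a cap-binding protein of oocytes, fell by 53.8 points, Casc3, of the exon junction complex, fell by 47.8 points, and Pabpc2, a poly(A)-binding protein, fell by 45.3 points. Vwa5a fell by 51.7 points and Ms4a15 fell by 43.3 points.

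Among the genes of the methylation machinery, 3 of 13 measured passed over all genes, and the same number when adjusted over the list alone (2 higher, 1 lower). Tet1, an oxidase of methylated cytosine (chromosome 10, 62804570 to 62887469), fell from 22.1% ± 6.54 to 2.01% ± 1.28 (adjusted p = 0.00286). The de novo methyltransferase gene Dnmt3b rose by 18.7 points from 80.3% ± 5.82, and Tet3 rose from 84.1% ± 6.15 to 95.6% ± 1.54. Of 25 sirtuin and antioxidant genes, 2 fell, also when adjusted over the list alone: Ppargc1a, a coactivator of mitochondrial genes (chromosome 5, 51454249 to 52115853), which fell by 19.5 points from 27.5% ± 5.45 (adjusted p = 0.00124), and the catalase gene Cat, which fell from 19.6% ± 6.04 to 1.66% ± 1.44. Among 20 polycomb-bound developmental genes, 4 fell, and 5 when adjusted over the list alone. These were Pax7 (chromosome 4, 139737059 to 139833530), a muscle stem cell factor, which fell from 14.1% ± 4.94 to 2.11% ± 1.14, Wt1, which fell by 10.0 points, Tbx5, which fell by 9.64 points, Lhx9, which fell by 8.56 points, and Gata6 over the list alone at 2.29% against 8.83%. Wt1, Lhx9 and Gata6 also act in somatic cells of the ovary. The meiotic genes Stra8 and Spo11 fell by 23.4 points and fell by 27.0 points, respectively, the only ones of 20 germline genes to pass, and also the only ones when adjusted over the list alone. Of 18 granulosa and cumulus cell genes, only Amh, the anti-Müllerian hormone gene, rose, by 36.8 points from 62.2% ± 11.8, and of 8 maternal imprint genes only Zrsr1, from 51.6% ± 28.6 to 95.7% ± 2.66. Both also passed when adjusted over their list alone. No paternal imprint gene (1 measured), oocyte gene (19) or spindle and checkpoint gene (19) passed over all genes or when adjusted over the list alone. No list held more called genes than the rest of the tested genes by Fisher's exact test (lowest p = 0.0867, polycomb-bound genes).

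The test covered 15595 gene bodies, 3516 of them under 0.05 before adjustment, and 1335 of the 1339 had groups that did not overlap. That held for 29.7% of all tested gene bodies, where chance gives 10%. The genome-wide exact permutation test gave p = 0.1, the smallest that 3 against 3 allows (adjusted p = 0.225 over 9 comparisons). The count was 319 without knockout control 2, 824 without control 1, 726 without resveratrol 3 and 840 by limma. It was 216 by limma after centring and 227 with all 7 groups in 1 fit. Of the 33 genes past the threshold that the naming rule took, 5 (Pax7, Ppargc1a, Ptcd3, Tet1 and Zfp422) passed whichever library was left out. Without controls 1, 2 and 3, 17, 6 and 21 passed, and 18, 18 and 17 without resveratrol libraries 1, 2 and 3. By limma 23 of the 33 passed, and 12 by limma after centring.

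In 6-month wild type oocytes, resveratrol and control libraries differed in no gene body at this depth. Genome-wide levels were 35.4% and 36.1%, a difference of −0.763 points ± 2.86 (SE, n = 3 and 3; exact permutation p = 0.9, adjusted p = 0.9). Over the left-out libraries it ran from −2.27 (without control 1) to 1.62 points (without resveratrol 2), and it was 0.280 without control 2. Tet2 had too few calls to be tested. The list members with the largest differences, none of which passed (adjusted p = 0.999), were Gata4 (52.1% ± 17.4 with resveratrol, 39.1% ± 34.3 in controls), Foxo3 (78.4% and 65.7%), Runx2 (a difference of −9.31 points), Tet1 (0.132% and 5.93%) and Fshr (13.6% and 17.4%). The sign turned for Foxo3 without control 3 (−9.24 points) and for Fshr without control 2 (2.99 points). Foxo3 is a regulator of follicle activation and Fshr the receptor for follicle-stimulating hormone. Only 2110 gene bodies could be tested by edgeR; 59 lay under 0.05 before adjustment, and limma also called 0. In simulated data for this comparison, 11% of changes of 20 points and 45% of changes of 40 points were recovered.

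In 10-month knockout oocytes, the resveratrol libraries lay slightly above the controls. Levels were 36.7% and 35.9%, a difference of 0.771 points ± 0.316 (SE, n = 3 and 2), and the groups did not overlap (exact permutation p = 0.2, adjusted p = 0.36, smallest possible 0.1). The difference was 0.488 points without control 2 and 1.05 without control 1. Over the 9656 sites with a call in every library the difference was −5.88 points, and over sites with at least 5 calls it was −7.84 points. At the latter sites control 1 stood apart at 48.0%, with control 2 at 22.0% and resveratrol 1 to 3 at 37.2%, 21.8% and 22.6%. Tet2 averaged 39.2% ± 15.4 with resveratrol and 71.9% ± 7.77 in controls and did not pass (adjusted p = 1). Dnmt3l, the cofactor of de novo methylation in oocytes, averaged 85.0% ± 9.88 and 48.9% ± 17.7, Kit, the receptor through which granulosa cells signal to the oocyte, 73.3% ± 9.39 and 40.3% ± 9.91, the cohesin gene Smc1b 68.5% and 39.4%, and Nlrp14 47.6% and 75.8%. None of these passed. Of 9053 gene bodies tested by edgeR 0 were called, with 295 under 0.05 before adjustment and 0 by limma; simulated changes of 20 and 40 points were recovered in 2% and 11% of genes.

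The next question was how methylation differed with the loss of Tet2. Knockout libraries were higher than wild type in all 3 strata of age and treatment, by 4.16 points on average (exact permutation test within strata over 4000 arrangements, p = 0.00925, adjusted p = 0.0278 over 3 factors). Most of it came from the 6-month controls, where knockout exceeded wild type by 8.95 points ± 2.47 (SE, n = 3 and 3; exact permutation p = 0.1, adjusted p = 0.225). With resveratrol the difference was 1.48 points ± 2.43 at 6 months (exact permutation p = 0.9, adjusted p = 0.9) and 2.04 points ± 0.717 at 10 months (n = 3 and 2; exact permutation p = 0.1, adjusted p = 0.225). At 6 months it was −0.906 without wild type resveratrol 2, 2.92 without wild type resveratrol 1 and 2.43 without wild type resveratrol 3, and at 10 months 1.13 and 2.95 without wild type resveratrol 1 and 2. Without the stratum of 6-month controls, whose knockout libraries had the lower imprint levels given above, the stratified difference was 1.76 points (exact permutation p = 0.185). In the 6-month controls genotype cannot be told apart from depth, with 340709 to 436041 nuclear calls in wild type and 4941065 to 12257342 in knockout. With resveratrol these were 312695 to 4048818 and 3658940 to 7506751 at 6 months. At 10 months wild type was the deeper, with 8617723 to 9617539 against 1356626 to 8508490.

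The X chromosome was higher in knockout than in wild type, by 7.34 points on average, and by 12.9, 5.45 and 3.70 points in the 3 strata (exact permutation p = 0.0005, adjusted p = 0.0035). Group means of the X chromosome were 40.2% to 41.2% in the wild type groups, 53.1% in the 6-month knockout controls and 43.3% to 45.8% in the other knockout groups. This held with each of 17 libraries left out (adjusted p 0.00175 to 0.0175). Without the 6-month control stratum the difference was 4.58 points (adjusted p = 0.07). Relative to the autosomes of the same library, a measure chosen after the data had been seen, the X chromosome was 3.30 points higher in knockout (exact permutation p = 0.0225), and 2.91 points higher without the 6-month controls (exact permutation p = 0.035). The first p passed 0.05 no longer without 10-month wild type resveratrol 2 (2.51 points, exact permutation p = 0.0725), 6-month wild type control 2 (2.30, exact permutation p = 0.054) or 6-month knockout control 2 or 3 (3.20 and 3.32, exact permutation p = 0.0585 and 0.051). Protein-coding gene bodies, other annotated genes and intergenic DNA were higher in knockout by 3.30, 4.35 and 5.32 points (adjusted p = 0.0249 for each), CpG-dense regions by 2.58 points (adjusted p = 0.0501) and gene ends by 0.370 points (exact permutation p = 0.591). The calls for the 3 classes were lost without wild type resveratrol 2 (adjusted p = 0.0613) and without the 6-month control stratum (1.97, 1.23 and 1.47 points, adjusted p = 0.427). The differences in depth between genotypes given above apply to the X chromosome and these classes as well.

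**Figure D4:**
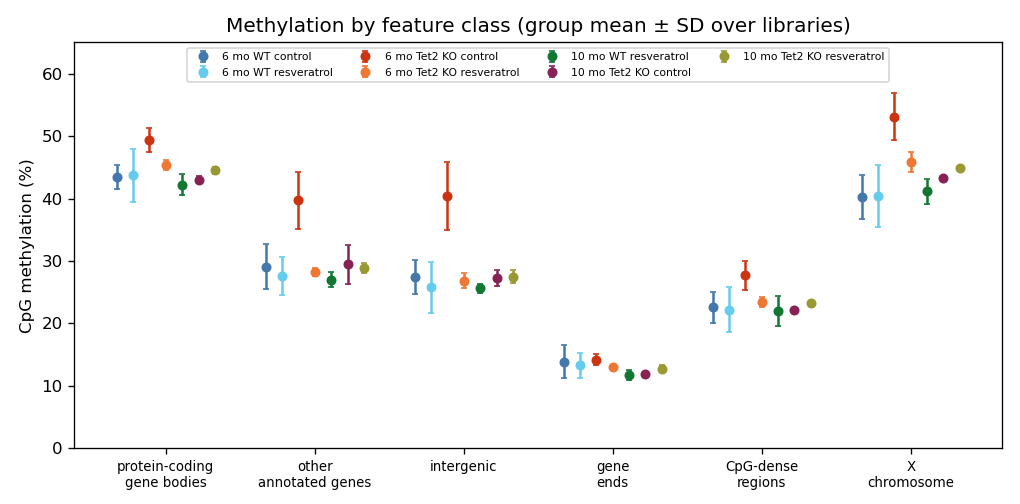
Methylation level (vertical axis, percent, group means with bars of 1 SD) of 6 classes of DNA (horizontal axis) in the 7 groups. Intergenic DNA averaged 40.4% in the 6-month knockout controls and 25.6% to 27.5% in the other groups.

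In the 6-month controls, Tet2 had too few wild type calls to be tested. The germline gene Hormad2 averaged 83.2% ± 4.72 in knockout and 46.9% ± 24.1 in wild type, Fshr 39.9% and 17.4%, Tex14, a protein of germ cell bridges, 46.2% and 66.8%, Kit 70.2% ± 13.4 and 91.0% ± 12.3, and the steroidogenic regulator Nr5a2 66.4% ± 2.01 and 95.6% ± 7.70. None passed over all genes. Adjusted over the list alone, Pax7 was higher in knockout by 14.1 points (adjusted p = 0.00554, 1 of 6 polycomb-bound genes), Nr5a2 was lower (adjusted p = 0.0295, 1 of 3 granulosa genes), and Kit, the only oocyte gene measured, was lower (adjusted p = 0.0446). Imprint regions could not be compared at this depth, with 7, 0 and 1 calls in the wild type controls. Of 3016 gene bodies tested, edgeR called 0, with 576 under 0.05 before adjustment, a smallest adjusted p of 0.0655 and 0 by limma; 168 were called with all 7 groups in 1 fit. Simulated changes of 20 and 40 points were recovered in 18% and 93% of genes, at a spread estimated in the knockout controls alone.

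With resveratrol at 6 months, no gene body was called between knockout and wild type at this depth, and recovery was not simulated. The energy sensor subunit gene Prkaa2 averaged 24.6% in knockout and 9.41% in wild type, Snrpn 59.4% and 49.8%, Dnmt3a 65.5% and 75.3%, Gata4 35.0% and 52.1%, and Kit differed by −20.8 points from 90.8% ± 10.1, none of which passed (adjusted p = 0.997). Snrpn turned to −1.02 points without wild type resveratrol 2. Tet2 was not testable, and edgeR called 0 of 3347, with 97 under 0.05 before adjustment and 0 by limma; it called 1 without knockout resveratrol 1. With resveratrol at 10 months, Tet2 averaged 39.2% ± 15.4 in knockout and 41.2% ± 4.04 in wild type, and the sign turned without knockout resveratrol 1 (6.81 points) or wild type resveratrol 1 (0.870 points). The sites compared differ, as 38 of 202 and 33 of 485 wild type calls lay in the interval without knockout calls. The mitotic kinase genes Aurka (75.6% and 48.1%) and Plk1 (72.0% and 45.8%), the mitochondrial sirtuin gene Sirt3 (76.1% and 52.5%), the meiotic cohesin gene Stag3 (43.9% and 67.0%) and Lhx8 (26.9% and 52.1%), a factor of early follicles, had the largest differences without passing (adjusted p = 1). EdgeR called 0 of 12755, with 333 under 0.05 before adjustment and 0 by limma, and 2 were called without wild type resveratrol 1. Simulated changes of 20 and 40 points were recovered in 0% of genes.

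The last question was whether methylation changed between 6 and 10 months. In knockout controls 381 gene bodies passed, 36 more and 345 less methylated at 10 months. Those that fell had a median of 3.24% at 10 months and 24.0% at 6 months, and of 4.44% in the 6-month knockout resveratrol libraries; those that rose had medians of 97.6% and 72.0% at 10 and 6 months. The genome-wide level was 35.9% at 10 months and 45.1% at 6 months, a difference of −9.19 points ± 2.50 (SE, n = 2 and 3; exact permutation p = 0.1, the smallest possible, adjusted p = 0.225), and intergenic DNA was at 27.3% and 40.4%. The 6-month libraries were again the knockout controls with 74.1% to 86.5% at the maternal imprint regions, where the 10-month controls read 98.0% and 98.0% over 150 and 49 calls.

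Tet2 averaged 71.9% at 10 months and 58.2% at 6 months and did not pass (adjusted p = 0.674). The largest rises were in Urad, of urate breakdown, from 20.1% ± 8.98 to 95.4% ± 0.293 (SD, n = 3 and 2; adjusted p = 0.0245), in Kptn by 73.3 points, the DNA helicase gene Pif1 by 68.9 points, the mitochondrial phosphatase gene Pgam5 by 66.5 points, and Ripk4 by 63.4 points. Nol9, of ribosomal RNA processing, Adat3, of transfer RNA editing, Mapkapk2, Brap and Prodh, of proline breakdown, rose by 54.6, 53.1, 50.5, 50.5 and 48.8 points. The largest fall was in Pno1, of ribosome assembly, from 91.6% ± 11.4 to 21.6% ± 5.61 (adjusted p = 0.0427). Arid5b fell by 51.1 points, the microtubule-end gene Mapre3 fell by 48.5 points, Myo7a fell by 42.1 points and Specc1 fell by 38.4 points. The meiotic recombination gene Mei1 fell by 36.7 points, Miga1, of mitochondrial fusion, fell by 35.3 points, Irak3 fell by 35.0 points, Dok2 fell by 33.8 points and Sh2b2 fell by 33.8 points.

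Among the fixed lists, Tet1 fell from 22.1% ± 6.54 to 1.90% ± 2.69 (1 of 12 machinery genes), Ppargc1a from 27.5% ± 5.45 to 8.05% ± 1.38 (1 of 15 sirtuin and antioxidant genes) and Pax7 from 14.1% ± 4.94 to 2.52% ± 1.68 (1 of 16 polycomb-bound genes). Adjusted over the list alone these 3 passed, and so did Tet3 (98.7% and 84.1% at 10 and 6 months), Cat (0.893% and 19.6%), Nr5a2 (88.6% and 66.4%) and Runx2 (14.5% and 35.8%), the last pair among 7 granulosa genes. No maternal imprint (6), paternal imprint (1), oocyte (9), germline (12) or spindle gene (15) passed, over all genes or adjusted over the list alone. The same 6-month controls served in the resveratrol comparison: of 10066 gene bodies tested in both, 310 were lower in both, 10 higher in both and 0 opposite, an overlap for which no value without effect was simulated. The correlation of the differences was 0.556 across genes, which are not independent replicates, against 0.403 to 0.435 in 20 simulations with shared controls and no effect. Those simulations drew genes independently at the spread of the 6-month knockout resveratrol libraries, without shifts of whole libraries. They therefore cannot tell whether the shared controls alone give 0.556.

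EdgeR tested 10300 gene bodies, with 2259 under 0.05 before adjustment, and limma called 0. Without 6-month control 1 the count was 0, without control 2 it was 8, without control 3 it was 248, and without 10-month control 1 it was 1055 (422 higher, 633 lower). Of the 23 genes named as past the threshold, 0 passed without 6-month control 1 or 2, 8 without control 3, 18 without 10-month control 1 and 13 without 10-month control 2.

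In knockout resveratrol libraries, no gene body was called between 10 and 6 months, with genome-wide levels of 36.7% and 36.9% (−0.182 points ± 0.389, SE, n = 3 and 3, exact permutation p = 0.8, adjusted p = 0.9). It ran from −0.496 (without 6-month resveratrol 1) to 0.0950 points (without 6-month resveratrol 2) over the left-out libraries. Tet2 averaged 39.2% and 32.8%. The antioxidant enzyme gene Gpx4 averaged 30.3% ± 24.6 and 3.13%, Uhrf2 36.0% and 59.1%, Tle6, of the subcortical maternal complex, 53.2% and 77.3%, the centromeric histone gene Cenpa 41.2% and 65.5%, and Sgo2a, a protector of centromeric cohesion, 31.2% and 57.7%. None passed (adjusted p = 1). EdgeR called 0 of 12298, with 370 under 0.05 before adjustment and 0 by limma. Recovery was not simulated for the age comparisons of resveratrol libraries, so 0 calls do not show equal levels. In wild type resveratrol libraries the levels were 34.6% and 35.4% (−0.738 points ± 3.18, SE, n = 2 and 3; exact permutation p = 0.9, adjusted p = 0.9), and the sign turned without 10-month library 1 (0.169), 6-month library 1 (0.700) or 6-month library 3 (0.210), while it was −3.13 without 6-month library 2. Prkaa2 averaged 24.4% and 9.41%, Foxo1 49.3% and 60.8%, Sirt1 10.3% and 27.2%, Dnmt3a 51.3% ± 0.105 and 75.3% ± 6.17, and Kit 57.6% and 90.8%, at 10 and 6 months, and none passed. The sign turned for Sirt1 without 6-month library 1 (6.57 points) and for Foxo1 without 6-month library 2 (4.74 points). Tet2 was not testable; edgeR called 0 of 3358, with 87 under 0.05 before adjustment and 0 by limma, and 1 without 10-month library 1.

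Whether the effect of resveratrol differed between ages or genotypes was examined next. The genome-wide permutation moved treatment labels within strata, so its null was no resveratrol effect in either stratum and not an equal effect in both. In knockout oocytes the difference between resveratrol and control was 9.01 points higher at 10 than at 6 months (exact permutation over 200 arrangements, p = 0.01, adjusted p = 0.02), and 156 of 8929 gene bodies passed, 150 of them with a higher and 6 with a lower effect at 10 months. Before adjustment 1682 lay under 0.05, and limma called 0. Both values include the 6-month knockout controls, with 74.1% to 86.5% at the maternal imprint regions. The count was 100 and 45 without 10-month control 1 and 2, 20 without 10-month resveratrol 3, 31 and 26 without 6-month control 1 and 2, and 52, 37 and 40 without 6-month resveratrol 1, 2 and 3. Between genotypes at 6 months, the resveratrol difference of knockout minus that of wild type was −7.47 points (exact permutation p = 0.135, adjusted p = 0.135). EdgeR called 0 of 2108 gene bodies for this, with 270 under 0.05 before adjustment and 0 by limma, though 3 were called without wild type control 2 and 1 without wild type control 3.

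Over all strata, resveratrol and control differed by −2.74 points (exact permutation p = 0.096, adjusted p = 0.096), and 10 and 6 months by −3.37 points (exact permutation p = 0.086, adjusted p = 0.096). The first lay below the threshold without 6-month wild type control 1 (−3.24, exact permutation p = 0.049) or resveratrol 1 (−3.22, exact permutation p = 0.0495), and the second without 6-month wild type resveratrol 2 (−4.16, exact permutation p = 0.00667). By stratum the age difference was −9.19 points in knockout controls, −0.182 in knockout resveratrol and −0.738 in wild type resveratrol libraries. Without the stratum of the 6-month knockout controls, the resveratrol difference was 0.00425 points and the age difference −0.460 points (exact permutation p = 0.82 for age), and neither passed. No class of DNA passed for resveratrol (other annotated genes −4.52 and intergenic DNA −5.01 points, adjusted p = 0.109) or for age (gene bodies −2.93 points, adjusted p = 0.113).

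Of the 9 gene lists, the oocyte genes and the methylation machinery genes were lower at 10 than at 6 months, with differences of −8.96 and −6.27 points (exact permutation p = 0.004 and 0.006, adjusted p = 0.027 for both). Neither passed relative to all gene bodies of the same library (−6.03 and −3.34 points, exact permutation p = 0.0665 and 0.312). Both calls were lost without either 10-month wild type library, 10-month knockout control 2 or knockout resveratrol 1, or without any 6-month knockout library, except that the machinery call was kept without 6-month control 3 (adjusted p up to 0.208 and 0.101). Over the left-out libraries the differences ran from −10.8 to −7.12 and from −7.08 to −4.80 points. Without the stratum of the 6-month knockout controls the differences were −7.59 and −8.45 points and passed no longer (adjusted p = 0.36 and 0.135). Between knockout and wild type, the levels of oocyte genes and polycomb-bound genes differed by −4.85 and 0.0072 points, and neither passed. All gene bodies were 3.30 points higher in knockout. The polycomb call that follows therefore reflects that rise and not a lower level of the list. Relative to all gene bodies, oocyte genes and polycomb-bound genes were lower in knockout than in wild type, with differences of −8.14 and −3.29 points (exact permutation p = 0.00725 and 0.01, adjusted p = 0.045 for both). Each was lost without either 10-month wild type library, 6-month wild type control 1 or 3, wild type resveratrol 3, 10-month knockout resveratrol 1, or any of 6-month knockout control 1, control 2 and resveratrol 1 to 3 (adjusted p up to 0.172 and 0.128). The oocyte call was also lost without 6-month knockout control 3, and the polycomb call without wild type resveratrol 2 or 10-month knockout resveratrol 3. Their differences ran from −9.49 to −6.68 and from −4.04 to −2.86 points over the left-out libraries. Without the 6-month control stratum neither passed (−7.69 and −3.57 points, adjusted p = 0.255 for both). For resveratrol no list passed; granulosa genes had the smallest p, at −5.68 points (exact permutation p = 0.0388, adjusted p = 0.349). The stratified resveratrol differences of the other lists were 1.19 points for oocyte, 0.0710 for machinery, −0.356 for sirtuin and antioxidant, −5.55 for germline, 0.207 for polycomb-bound and 3.28 for spindle genes. The imprint lists gave 9.17 points (maternal) and −19.0 (paternal), but the 6-month wild type controls held only 26 to 39 and 5 to 12 calls there, with paternal levels from 0% to 100%, and 1 of the 2 10-month knockout controls held no paternal call.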

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

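The tests of library depth, of wild type DNA, of the genes called with age and of conversion over whole libraries, together with the subset of 8 imprint regions, were chosen only after the result was seen, and those at CpG-dense regions methylated in oocytes after the imprint levels, though not their own values, were seen.

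In Tet2 knockout oocytes the effect of resveratrol on the genome-wide level was 9.01 points higher at 10 than at 6 months (exact permutation p = 0.01), and 156 gene bodies passed the interaction in edgeR. Both values include the 6-month knockout controls, the libraries of the first pattern. The permutation moved treatment labels within each age, so its null was no effect at either age and not an equal effect. The count was 45 and 100 without 10-month control 2 and 1, 20 without 10-month resveratrol 3, 31 and 26 without 6-month control 1 and 2, and 52, 37 and 40 without 6-month resveratrol 1, 2 and 3.

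The first pattern is the higher methylation of the 6-month knockout controls than of the 6-month knockout resveratrol libraries. Against library depth as the cause, the 5 libraries outside these controls with at least as many calls as the shallowest control (7506751 to 9617539 calls) read 33.7% to 37.0% (SD 1.34), the highest of them 5.22 points below the lowest control. Among the 3 controls the level rose with depth (42.2%, 44.4% and 48.7% at 4941065, 5496410 and 12257342 calls), which was not tested. A planned test by thinning was dropped, since thinning cannot move a pooled level. Against incomplete conversion, CpG-dense regions of polycomb-bound genes differed by only 0.227 points ± 1.19 (SE) while intergenic DNA differed by 13.6. Dense regions at 10% or less in the reference libraries rose by 3.99 points ± 0.980 (SE), so conversion as a part of the difference is not excluded, though it would not lower the regions methylated in oocytes. Against wild type DNA as the whole cause, in a Tet2 interval chosen in the other 8 knockout libraries the 3 controls held 4 calls where 109 were expected, with an upper 95% limit of 8.37% for its share if calls are independent. Against a gain in the oocytes alone, as from loss of Tet2 reversed by resveratrol, regions methylated in oocytes were lower by −6.69 points ± 1.60 (SE). What stays open is DNA of somatic cells, such as cumulus cells left after hyaluronidase and pipetting. Such DNA may lower the maternal imprints (−17.0 points ± 3.62, SE, at the 8 regions) and the dense regions methylated in oocytes (−6.69 points) and raise intergenic DNA together, as was seen. Over the whole planned maternal list the difference was −15.6 points ± 3.26 (SE), but that list did not set these controls apart. They read 51.9% to 55.4% there, the lowest 10-month knockout control read 53.5%, and the 6-month wild type controls averaged 35.4% over 26 to 39 calls each. Methylated H19 calls came from control 2 alone, though controls 1 and 3 held only 10 and 6 calls there. A biological change of some other kind, with losses as well as gains and with imprints affected, was not tested.

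The second pattern is the 381 gene bodies that differed between 10-month and 6-month knockout controls. Those lower at 10 months had a median of 4.44% in the 6-month knockout resveratrol libraries (quartiles 3.29% to 7.53%), close to 3.24% in the 10-month controls and far from 24.0% in the 6-month controls. The 6-month resveratrol libraries thus did not share the high levels of the 6-month controls at these gene bodies. The gene bodies were chosen for high levels in those controls, and 310 of them were also called lower with resveratrol. This outcome was thus largely set in advance. It lends no weight to somatic DNA in the 6-month controls, which stays a candidate source. Nor does it separate such DNA from a difference that resveratrol removes. The test replaced an earlier one on baseline levels, which had met its own prediction but whose outcome the choice of 10-month reference libraries largely fixed. The calls number 0 without 6-month control 1 and 8 without control 2, and a change with age in mice without resveratrol alone stays open as untested.

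The third pattern lies in mitochondrial DNA, outside the main measurement, where 26.4% to 64.6% of CpG calls read as methylated, the highest in 10-month knockout resveratrol 1 over 567806 calls. Mitochondrial DNA that converted poorly at all of its sites might give this: a median of 77.8% of sites lay within 15 points of the library's level, between the bounds set for and against it, and 46.5% in that library. Against poor conversion of whole libraries as the cause, CpG-dense regions of polycomb-bound genes in the same libraries read 1.30% to 10.9%, and in every library the mitochondrial level lay at least 17.4 points above the upper 95% binomial limit there. This test replaced a correlation of both levels over 19 libraries (Spearman's rho 0.221, permutation p = 0.359), which fell between the bounds set for it. Poor conversion limited to mitochondrial DNA cannot be told apart from methylation of that DNA, as the share of sites near the library's level fell between its bounds. No biological explanation was tested.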

How the results depend on the processing

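The mean over 100-kb windows, the level with mitochondrial calls, the strata without the 6-month knockout controls and the left-out libraries for classes and lists were tests chosen only after the result was seen. Depth left 977 to 71138 sites per comparison with a call in every library. The counts of the 2 comparisons with called genes were not rerun without all 6-month knockout controls, since no group would remain. Groups of 2 or 3 were too small to test a sample as an outlier. Except where stated, the cause of a changed value was not tested.

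For the genome-wide level, the resveratrol difference in 6-month knockout, the genotype differences in 6-month controls and 10-month resveratrol libraries, and the age difference in knockout controls kept their direction under every alternative run; their groups are too small to pass 0.05. The genome-wide interactions were not rerun. Over sites with at least 5 calls, the sign turned for resveratrol in 10-month knockout (−7.84), genotype with resveratrol at 6 months (−0.530), age in knockout resveratrol (4.94) and age over all strata (1.18). Over sites with a call in every library it turned for the first 3 (−5.88, −0.339 and 5.10) and for age in wild type resveratrol (1.71), which also turned with the mean of per-site levels (0.908). At sites with at least 5 calls, 10-month knockout control 1 read 48.0% and 10-month knockout resveratrol 1 read 37.2%. The other knockout libraries of the resveratrol comparison at 10 months and of the age comparison with resveratrol read 20.5% to 23.8%. The mean over windows turned genotype with resveratrol at 6 months (−0.320) and age in knockout resveratrol (0.169), and mitochondrial calls turned the latter (3.39). The genotype difference over all strata passed under every alternative run except without the stratum of the 6-month knockout controls (1.76), where that of resveratrol also turned (0.00425) and that of age was −0.460, with fewer libraries. With 1 library left out, ranges were −2.27 to 1.62 for resveratrol in 6-month wild type, 0.488 to 1.05 for resveratrol in 10-month knockout, −0.906 to 2.92 and 1.13 to 2.95 for genotype with resveratrol at 6 and 10 months, −0.496 to 0.0950 and −3.13 to 0.700 for age in knockout and wild type resveratrol, −3.24 to −1.95 for resveratrol and −4.16 to −2.76 for age over all strata.

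For gene bodies, the 1339 called for resveratrol in 6-month knockout were 840 (52 higher, 788 lower) by limma, 216 (18 and 198) by limma after centring, 227 with all groups in 1 fit, 612 with at least 20 points, and 7433 as windows. The 381 for age in knockout controls were 0 by limma with or without centring, 41, 215 (fewer genes by construction) and 3885 as windows. The 156 of the interaction with age were 315 and 94 with minimums of 20 and 1 calls, 0 by limma and 1 after centring. For genotype in 6-month controls, minimums of 20 and 1 calls gave 4 and 1, all groups in 1 fit 168, centred limma 2, windows 1 and exclusion of extreme depth 1; age in knockout resveratrol gave 4 windows. With 1 library left out, the counts ran from 319 to 1114, from 0 to 1055 and from 20 to 198 for those 3 sets, from 0 to 1 for genotype with resveratrol at 6 months and age in wild type resveratrol, 0 to 2 for genotype at 10 months, and 0 to 3 for the interaction with genotype. Of 1248 values of named genes under alternatives, 949 stayed on their side, 291 no longer passed and 8 turned by the sign of the odds ratio in edgeR.

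With 1 library left out, the difference of Foxo3 ran from −9.24 to 26.4 and that of Fshr from −8.18 to 2.99 (resveratrol, 6-month wild type), that of Snrpn from −1.02 to 16.8 and that of Tet2 from −7.30 to 6.81 (genotype with resveratrol, 6 and 10 months), and those of Sirt1 and Foxo1 from −28.9 to 6.57 and from −21.4 to 4.74 (age, wild type resveratrol). Foxo3 was also 3.34 without 6-month wild type resveratrol 3, where the odds ratio turned but the difference in points did not, and Tet2 0.870 without 10-month wild type resveratrol 1.

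The labels share replicate numbers between groups. Same-numbered libraries correlated in their deviations at −0.0274 to 0.0557, never above 0.1, and the numbers were not taken as pairs. Counting noise at this depth can keep such correlations low even in pairs, so pairing is not excluded. In 6-month wild type each of the 3 resveratrol libraries correlated best with its own number, and in no other comparison with 3 pairs did every one. With the replicate block the interaction with age called 16, and counts of 0 became 1 (resveratrol in 10-month knockout), 11, 1 and 9 (genotype in 6-month controls, with resveratrol at 6 and at 10 months). The genome-wide age difference in wild type resveratrol was 0.210, 21 values of named genes no longer passed, and no other count of calls moved by more than 1.5 times.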

Other observations

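The tests on the X chromosome relative to the autosomes were chosen only after the result was seen.

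The fixed lists differed in level within the oocyte genome more than most groups differed from each other. In 6-month knockout resveratrol libraries, genes of the spindle, cohesion and checkpoint list averaged 69.9%, those of the methylation machinery 60.7%, oocyte genes 49.8%, germline genes 39.9% ± 4.12, sirtuin and antioxidant genes 38.2%, granulosa and cumulus genes 28.5% ± 1.89 and polycomb-bound developmental genes 9.34% ± 1.44 (SD, n = 3). The 6-month knockout controls gave 69.4%, 58.4%, 53.5%, 48.6% ± 2.57, 42.2%, 36.8% ± 3.27 and 12.3% ± 1.01 for the same lists. Thus 5 of these 7 lists lay higher in the controls, and spindle and machinery genes, the most methylated, lay slightly lower. At the CpG-dense regions of the imprint lists, maternal imprints averaged 69.7% ± 5.31 with resveratrol and 54.1% ± 1.91 in controls, and paternal ones 27.5% ± 3.96 and 41.0% ± 3.64.

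The X chromosome exceeded the autosomes of the same library by 4.21 to 6.74 points in the 3 wild type group means and by 7.65 to 9.28 points in the 4 knockout group means, but single wild type libraries overlapped the knockout ones: the 6-month wild type controls ran from −1.78 to 10.7 points (SD 6.26, n = 3) and 10-month wild type resveratrol libraries from 4.37 to 9.10. Mitochondrial calls differed between ages by 10.2 points in their methylated share, higher at 10 months (exact permutation p = 0.027, adjusted p = 0.113), and between genotypes by 2.37 points.

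For the 5 comparisons of 3 against 3 libraries, the 10 splits cannot give a share under 0.05. Resveratrol against control in 6-month knockout called 1339 gene bodies in the real split, 1 of 10 splits with as many, and 0 in the highest other. Resveratrol against control in 6-month wild type, and knockout against wild type in 6-month controls and in 6-month resveratrol libraries, called 0 in the real split and 0 in the highest other. Between 10 and 6 months in knockout resveratrol libraries the real split called 0 and the highest other 1.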
